A study of Mus musculus with 16 samples.

How the data were processed

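Female C57BL/6 mice, 6 weeks old, were infected with cercariae of Schistosoma japonicum, the larval stage released by the snail host. Regions of frozen liver were cut out by laser microdissection, so each sample is a piece of a zone and not a sorted cell population. Total RNA was isolated with Trizol and RNeasy columns, amplified to cRNA and read with Cy3 on Illumina mouse BeadArrays. There were 16 arrays, 2 mice for each of 8 groups, all used. Per the file headers the 16 arrays sat on 2 slides of 8, with replicate 1 of every group on 1 slide and replicate 2 on the other, so replicate number and slide cannot be separated.

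The deposited signal table holds 1 intensity per probe and array, not normalised and without background subtraction, from 70.3 to 70485.5. GenomeStudio 1.1.1 is named in the submitters' processing notes. Beside each intensity the deposited table has a detection p-value column, whose numbers are 1 minus the p-value, as their relation to the intensities shows. The authors' processed value table is on a log2 scale. It was recomputed as the log2 intensity minus the 75th percentile of the array, minus the median of the probe over all 16 arrays, to within 0.0003. Mean intensity per array ran from 130.2 to 705.0. No more than 0.377% of intensities were equal between any pair of arrays, so no array was a copy of another.

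Intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc estimated background from the detection p-values, corrected with an offset of 16, applied quantile normalisation and took log2. Probes were kept where the detection p was under 0.01 on both arrays of at least 1 group, which left 11583 of 25697. Gene symbols came from the platform's probe table, updated through the mouse gene annotation of assembly GRCm38.p6, which changed 0 symbols. A single symbol was given for 23978 probes, and 1719 had none and are not analysed here by name. The probe with the highest mean represented each gene, leaving 8394 genes. No coordinates are reported.

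A linear model of 8 group means was fitted over all 16 arrays with limma, moderated by eBayes (residual degrees of freedom 8, prior degrees of freedom 4.19). Pooling the spread over all groups assumes that it is alike, while the dim arrays vary more. The 16 comparisons were 7 tissues against uninfected liver, 5 between zones, 3 between weeks and the interaction of zone and week. A gene was called when its Benjamini-Hochberg adjusted p, two-sided and over all genes within a comparison, was under 0.05. The comparisons against uninfected liver share its 2 arrays, so their overlaps are not reported. Every called gene of every comparison between groups had the same sign on both slides. An array's detection level was the lowest normalised value among its probes with a detection p under 0.01. Where an array of the lower group did not detect a gene, its value was raised to that array's level before averaging. The fold is then given as a lower bound, and it is withheld where the other group's mean does not exceed that level or where neither group detected the gene. Arrays of the higher group that did not detect a gene kept their normalised values, so a fold resting on such an array is not a strict bound. Of the calls counted as having a usable fold, 4 in the 6-week core, 4 in the 6-week outer zone and 8 between the 6-week core and the 4-week granuloma had no bound above 1.

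The question, the tests, the alternatives, 34 gene lists for cell types and functions and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members, 30 of them, were tested with limma's camera at a preset correlation of 0.01 and adjusted over lists within a comparison. Camera with an estimated correlation and fry were run beside it. Genes named are the 5 with the largest rise and the 5 with the largest fall among called genes whose arrays do not overlap between groups, up to 4 called members of each list described or else the member with the smallest p, and a panel of 32 genes. Of this panel, Ear11 and Spp1 had no probe with that symbol and Ccl17 was not tested.

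The pipeline was tested on simulated data in which 200 of 8394 genes were changed by a known amount and the noise matched each group's spread. It recovered 14% to 46% of genes changed by 2 log2 units and 78% to 98% of those changed by 4. The share of calls that were unchanged genes ranged from 0% to 78.0% and was highest where both groups had a dim array. This share depends on how many genes change, so it is not an error rate of the real calls. Alternatives were other background corrections, median scaling, the authors' value table, other detection filters, every probe tested, a replicate block (which is also the slide block), a replicate block within each week, only the groups compared, a trended robust eBayes, array weights, a 2-fold minimum, an adjusted p under 0.01 and leaving out each array in turn. As a check for shared mice, the deviation of replicate 1 from its group mean was correlated across genes between groups. Over 28 pairs of groups it was highest in pairs of the same week, 0.392 for core and outer zone at 6 weeks, where replicate 1 of both was dim, and 0.294 for outer zone and periphery at 7 weeks. The other 3 pairs of the same week lay between 0.0135 and 0.106, and all other pairs between -0.216 and 0.229. Genes are not independent replicates, and the mice behind each zone remain unknown. Added after the data had been seen were a fit without the 3 dimmest arrays and a count of only those genes with a usable fold.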

Results

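Gene expression was measured on single-colour Illumina mouse BeadArrays, glass slides on which each transcript is read by beads carrying 1 probe sequence. The samples were pieces of liver cut out by laser from frozen sections of female C57BL/6 mice infected with Schistosoma japonicum, a blood fluke whose eggs lodge in the liver and become enclosed in granulomas. There were 16 arrays in 8 groups of 2 mice each: uninfected liver, the 4-week granuloma, the liver around it, the core (zone 1) and outer zone (zone 2) at 6 weeks, and the core, outer zone and periphery (zone 3) at 7 weeks. The series asks what part neutrophils play in forming the granuloma, so each tissue was compared with uninfected liver, and the zones and weeks with one another. Whether zones of 1 week came from the same mice is not stated in the labels.

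The arrays differed widely in signal. Probes detected above background ranged from 1275 on replicate 2 of the 4-week granuloma to 11248 on replicate 1 of the 7-week periphery, out of 25697. The other dim arrays were replicate 1 of the 6-week core, with 2305 probes, and replicate 1 of the 6-week outer zone, with 3442. The SD between replicates, pooled over genes, was 0.297 log2 units in uninfected liver and 1.20 in the 4-week granuloma, 1.07 in the 6-week core and 0.839 in the 6-week outer zone. With 2 mice per group the number of arrays limits the precision of every value. Where an array of the lower group did not detect a gene, the change is given as at least N-fold or withheld, as described above. A fold resting on an undetected array of the higher group is not a strict bound. Quantile normalisation, which gives all arrays the same distribution of values, left the median gene close to its uninfected level, from -0.45 log2 units in the 4-week granuloma to 0.22 in the 7-week outer zone. Scaling each array by its median instead left it at -2.19 in the 4-week granuloma, -1.06 in the tissue around it, -1.70 and -1.23 in the 6-week core and outer zone, and -1.56, -0.19 and -0.12 in the 7-week core, outer zone and periphery. Changes are given relative to the quantile scale.

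**Figure D1:**
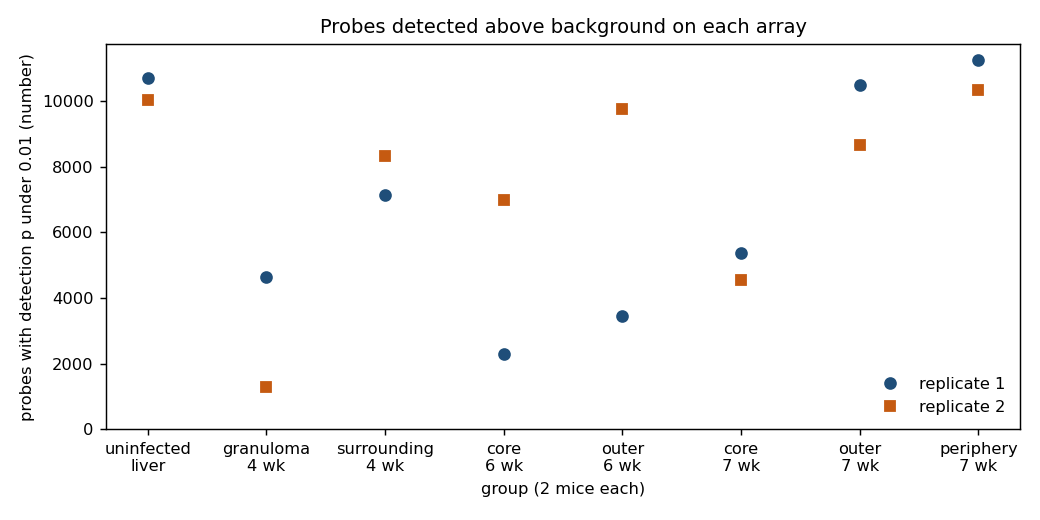
Probes with a detection p under 0.01 on each array (vertical axis, number of probes) by group, 1 point per array with replicate 1 and replicate 2 marked. The lowest point is replicate 2 of the 4-week granuloma at 1275 and the highest is replicate 1 of the periphery at 11248.

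The first question was which genes distinguish young lesions at 4 weeks from healthy liver. Genes called higher included chemokine, class II antigen-presentation and cytotoxic genes, but no list kept its call with an estimated correlation. Cxcl9, an interferon-induced chemokine for T cells, was 19.2-fold higher, with a log2 difference of 4.26 ± 0.89 SE, and Ccl5 was 12.3-fold higher. Class II genes called higher were H2-Aa (11.9-fold) and H2-Eb1 (12.6-fold). The killer-cell genes Prf1 (10.8-fold) and Ctsw (at least 9.15-fold), the T-cell genes Foxp3 (at least 9.40-fold) and Cd8b1 (at least 4.77-fold) and the interferon-induced Oasl2 (9.24-fold) and Gbp2 (8.29-fold) were also higher. Macrophage genes called higher included Clec7a (16.5-fold), Lgals3 (9.77-fold) and Ctss (6.03-fold), the matrix-degrading Mmp13 (at least 8.43-fold) and Mmp12 (at least 4.33-fold) and the chemokine Ccl7 (at least 5.36-fold). The fibrosis-related Acta2 (8.63-fold), Vim (8.15-fold) and Col3a1 (5.01-fold) were higher. Of 13 stellate-cell markers 2 were called each way, Reln and Pdgfra lower. With median scaling Ccl5, H2-Aa, H2-Eb1, Prf1, Oasl2, Gbp2, Clec7a, Lgals3, Ctss, Acta2, Vim, Col3a1 and Lcn2 lay below their uninfected level, at log2 differences from -1.54 for Lcn2 to -0.01 for Clec7a, while the median gene lay at -2.19. Foxp3, Cd8b1, Mmp13, Mmp12, Ccl7 and Col3a1 were detected on 1 granuloma array, so their folds rest partly on an undetected value. The largest rises also included Mid1 (at least 27.3-fold), Setd4 (21.9-fold), Arl9 (at least 20.1-fold) and Ormdl2 (at least 15.9-fold). Of the neutrophil genes, Lcn2 was 6.10-fold higher and S100a8 (log2 difference 0.22) was not called. Nor were S100a9 and Cxcl2, which no granuloma array detected. Genes called lower included the circadian regulator Dbp (at least 3.29-fold), the coagulation factor F5 (at least 1.53-fold), the drug-metabolising Cyp3a11 (at least 2.77-fold), the transporter Slco1b2 (at least 1.40-fold) and Glud1 (at least 2.38-fold), Tmprss6 (at least 2.56-fold), Akr1c12 (at least 1.64-fold) and Acot1 (at least 1.54-fold). With a replicate block Setd4, Arl9 and Cyp3a11 were not called (adjusted p = 0.0567, 0.0546 and 0.0516).

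Over all genes 671 of 8394 were called, 222 higher and 449 lower (33.1% higher, against 0.107% of 5621 with median scaling), and 389 of them had no usable fold. Without a detection filter 50.4% of calls were higher. Of the class II antigen-presentation genes 6 of 10 were called higher, and 6 adjusted over the list alone (camera adjusted p = 2.31e-07, and 0.0943 with an estimated correlation), and of the interferon response genes 5 of 21 were, and 8 over the list alone (2.31e-07, and 0.142). Of the macrophage markers 4 of 19 were called higher and 0 lower, and 6 and 1 adjusted over the list alone (camera adjusted p = 1.91e-04, and 0.0871 with an estimated correlation), and with the authors' value table their median turned from 0.80 to -0.58. Of the neutrophil markers 1 of 22 were called higher, and 2 adjusted over the list alone (camera adjusted p = 0.0269, and 0.556 with an estimated correlation). Of 30 lists tested, 15 passed camera and 0 kept the call with an estimated correlation. The call count depended on single arrays: it was 10 without uninfected replicate 1, 56 without uninfected replicate 2, 2827 without granuloma replicate 1 and 173 without granuloma replicate 2. It was 0 when only these 4 arrays were fitted and 0 with array weights. In simulated data 31.5% of calls were unchanged genes.

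The next question was whether the liver around the young granuloma differed from healthy liver. No gene was called by limma in this tissue (169 had an unadjusted p under 0.05), and camera placed interferon, class II, phagocyte and blood-cell genes above other genes. Camera's adjusted p was 8.94e-12 for the interferon response genes (0.189 with an estimated correlation), 3.18e-06 for the class II antigen-presentation genes (0.289), 0.0434 for the phagocyte oxidase and receptor genes (0.311) and 0.0189 for the erythroid and platelet markers (0.189), which did not pass without surrounding-tissue replicate 2. Adjusted over each list alone, 0 of their 21, 10, 23 and 7 genes were called. Cxcl9 was 6.48-fold higher, Prf1 4.80-fold and Mt1 3.16-fold, none of them called. The hepatocyte genes Cyp2e1 (log2 difference -0.59) and Cyp7a1 (log2 difference 0.65) and the neutrophil genes S100a8 (log2 difference 0.15) and Cxcl2, detected in neither tissue, were not called. Other choices of model or scaling called from 0 to 631 genes here, the most with the authors' value table (42.2% higher), 230 with array weights (42.6%), 9 with median scaling (0%) and 7 with a trended robust fit (28.6%).

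Comparing the 4-week granuloma with the liver around it asks what sets the lesion apart within an infected liver. The lesion held more of the matrix-degrading Mmp13 (at least 5.48-fold) and Mmp12 (at least 2.72-fold), the mesenchymal Vim (at least 6.73-fold) and the T-cell chemokine Ccl5 (6.70-fold). Mmp13 and Mmp12 were detected on 1 of the 2 granuloma arrays. The largest rises were Ormdl2 (at least 10.01-fold), Sftpd (at least 9.88-fold), Tead4 (at least 7.82-fold), Arhgap19 (at least 7.14-fold) and Grk4 (at least 5.70-fold). Genes called lower in the lesion included the carbonic anhydrase Car3 (at least 3.17-fold), the acyl-CoA hydrolase Acot1 (at least 2.39-fold), Cyp2b23 (at least 1.71-fold), F5 (at least 1.40-fold), A1bg (at least 1.49-fold), Slco1b2 (at least 1.24-fold) and Glud1 (at least 1.41-fold). The neutrophil genes S100a9 and Cxcl2, detected in neither tissue, and S100a8 and Il1b (log2 difference 0.07 for each) were not called.

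The lesion and its surroundings differed in 203 genes, 57 higher in the lesion and 146 lower (28.1% higher, against 0% of 319 with median scaling), of which 131 had no usable fold. Of the chemokines other than neutrophil attractants 1 of 17 were called higher, and 5 adjusted over the list alone (camera adjusted p = 2.57e-05, and 0.0983 with an estimated correlation), and of the metalloproteinases and inhibitors 2 of 19 were, and 3 over the list alone (3.26e-04, and 0.0848). Among the neutrophil markers, 0 of 22 were called higher and 0 lower, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.0414, and 0.560 with an estimated correlation). Camera passed 14 of 30 lists and 0 kept the call with an estimated correlation. This count was 2493 without granuloma replicate 1, 10 without granuloma replicate 2, 0 without surrounding-tissue replicate 1 and 0 without surrounding-tissue replicate 2, 0 when only these 4 arrays were fitted and 0 with array weights, and 28.6% of calls in simulated data were unchanged genes.

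For the mature lesion the question was what fills the core around the egg at 6 weeks. Neutrophil, chemokine and phagocyte genes were among the largest rises. The calcium-binding alarmin genes S100a9 (at least 690-fold) and S100a8 (599-fold) led the neutrophil genes, S100a9 with a log2 difference of 9.57 ± 0.44 SE. Further neutrophil genes were Retnlg (at least 208-fold), Hdc (169-fold), Clec4d (at least 164-fold), Lcn2 (80.7-fold), Csf3r (78.7-fold) and Mmp9 (at least 36.8-fold). Neutrophil-attracting signals rose alongside: Cxcl2 (at least 325-fold), Il1b (281-fold), Ccl3 (at least 234-fold) and Tnf (at least 20.8-fold). The monocyte chemokine Ccl4 rose at least 747-fold and the acute-phase gene Saa3 394-fold. Macrophage and phagocyte genes included Chil3 (at least 292-fold), Cd14 (156-fold), Clec7a (116-fold), Lgals3 (83.2-fold) and Nos2 (at least 17.6-fold). The matrix-degrading Mmp13 (at least 92.9-fold) and Mmp12 (at least 95.4-fold) and the protease inhibitor Timp1 (at least 99.4-fold) were higher, as were the glucose transporter Slc2a1 (54.8-fold) and the glycolytic Pkm (50.5-fold). Liver genes called lower included Cyp2e1 (at least 164-fold), Mup2 (at least 139-fold), Mat1a (at least 71.8-fold), Gnmt (at least 55.1-fold), Gsta3 (at least 41.9-fold), Mup6 (at least 91.02-fold), Cyp2c50 (at least 62.6-fold), Acaa1b (at least 54.8-fold) and Cps1 (at least 26.4-fold).

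The 6-week core differed from uninfected liver in 2266 genes, 856 higher and 1410 lower (37.8% higher, against 3.22% of 4416 with median scaling), with 349 lacking a usable fold. The neutrophil markers had 19 of 22 called higher, and 20 adjusted over the list alone (camera adjusted p = 1.96e-17, and 0.0378 with an estimated correlation), and of the neutrophil chemoattractants 6 of 8 were, and 6 over the list alone (2.08e-07, and 0.0251). Of the classically activated macrophage genes 10 of 11 were called higher, and 11 adjusted over the list alone (camera adjusted p = 3.39e-09, and 0.0127 with an estimated correlation). Of the phagocyte oxidase and receptor genes 20 of 23 were called higher, and 20 adjusted over the list alone (camera adjusted p = 9.77e-17, and 0.00190 with an estimated correlation). Of the hypoxia and glycolysis genes 10 of 16 were called higher and 1 lower, and 11 and 1 adjusted over the list alone (camera adjusted p = 4.53e-07, and 0.0548 with an estimated correlation). Of the hepatocyte markers 1 of 25 were called higher and 24 lower, and 1 and 24 adjusted over the list alone (camera adjusted p = 3.33e-13, and 0.0757 with an estimated correlation). Of the cytochrome P450 and xenobiotic genes 21 of 22 were called lower, and 22 adjusted over the list alone (camera adjusted p = 6.38e-13, and 0.0643 with an estimated correlation). Of 30 lists, 22 passed camera and 5 kept the call with an estimated correlation. In simulated data 10.3% of calls were unchanged genes.

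The same question was asked of the 7-week core, where inflammatory and neutrophil genes were again among the largest rises and collagens were also higher. Ccl4 (at least 884-fold), S100a9 (at least 744-fold), S100a8 (586-fold) and Saa3 (519-fold) were the first of these, Ccl4 with a log2 difference of 9.81 ± 0.75 SE. Neutrophil-attracting and inflammatory signals included Cxcl2 (at least 321-fold), Il1b (300-fold), Ccl3 (at least 261-fold) and Tnf (at least 29.2-fold), the prostaglandin enzyme Ptgs2 (at least 21.5-fold) and the anti-inflammatory cytokine Il10 (at least 17.4-fold). Neutrophil genes called higher included Retnlg (at least 241-fold), Hdc (156-fold), Clec4d (at least 155-fold), Lcn2 (77.3-fold), Csf3r (45.2-fold) and Mmp9 (at least 40.5-fold). Macrophage products were Chil3 (at least 268-fold), Cd14 (237-fold), Mmp12 (at least 174-fold), Lgals3 (99.2-fold) and Gpnmb (at least 71.6-fold). The protease inhibitor Timp1 (at least 238-fold), the fibrosis mediator Ccn2 (43.3-fold) and the fibrillar collagens Col1a2 (24.2-fold) and Col3a1 (20.9-fold) were higher. Liver genes called lower included Cyp2e1 (at least 196-fold), Apoc3 (at least 192-fold), Crp (at least 71.6-fold), Apoa2 (at least 202-fold), Ces1c (at least 120-fold), Mup6 (at least 114-fold), Gsta3 (at least 98.1-fold), Acaa1b (at least 68.6-fold) and Cps1 (at least 33.1-fold).

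At 7 weeks 2377 genes were called in the core, 993 higher and 1384 lower (41.8% higher, against 5.12% of 4125 with median scaling), and 307 had no usable fold. For the neutrophil markers, 18 of 22 were called higher, and 20 adjusted over the list alone (camera adjusted p = 3.06e-16, and 0.0479 with an estimated correlation). Of the neutrophil chemoattractants 6 of 8 were called higher, and 7 adjusted over the list alone (camera adjusted p = 1.89e-07, and 0.0241 with an estimated correlation). Among the phagocyte oxidase and receptor genes, 21 of 23 were called higher, and 22 adjusted over the list alone (camera adjusted p = 3.62e-15, and 0.00284 with an estimated correlation). Of the metalloproteinases and inhibitors 10 of 19 were called higher, and 10 adjusted over the list alone (camera adjusted p = 3.49e-07, and 0.00878 with an estimated correlation). Of the collagens and matrix genes 9 of 22 were called higher and 1 lower, and 9 and 1 adjusted over the list alone (camera adjusted p = 1.69e-04, and 0.185 with an estimated correlation). Among the hepatocyte markers, 1 of 25 were called higher and 24 lower, and 1 and 24 adjusted over the list alone (camera adjusted p = 5.29e-17, and 0.0685 with an estimated correlation). Of 30 lists, 20 passed camera and 6 kept the call with an estimated correlation. Leaving out arrays, the count was 1348 without uninfected replicate 1, 1487 without uninfected replicate 2 and 1552 without 7-week core replicate 2.

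**Figure D2:**
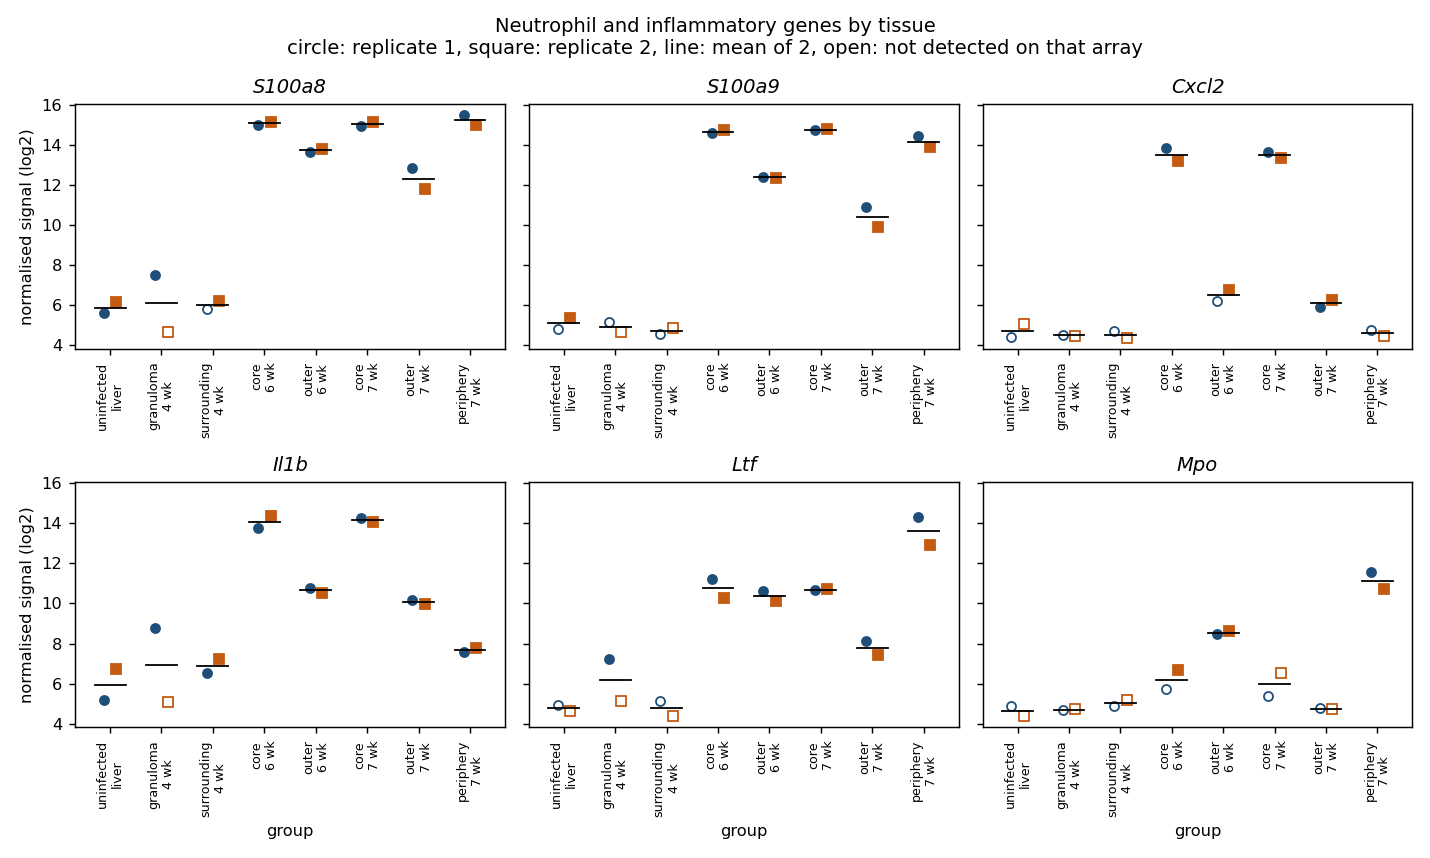
Normalised log2 signal (vertical axis) of S100a8, S100a9, Cxcl2, Il1b, Ltf and Mpo in the 8 groups, 1 point per array with a line at the group mean and open points where the array did not detect the gene. S100a8 was high in every zone at 6 and 7 weeks, Cxcl2 and Il1b were highest in the cores, and Ltf and Mpo were highest in the periphery.

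For the outer zone the question was what surrounds the core at 6 weeks. The 6-week outer zone had more collagen transcripts and also held neutrophil transcripts. The protease inhibitor Timp1 was at least 386-fold higher, and the fibrillar collagens Col1a2 (165-fold), Col1a1 (at least 107-fold), Col3a1 (109-fold) and Col5a1 (100-fold) rose with the collagen cross-linker Lox (at least 38.05-fold). Contractile and mesenchymal genes were higher, including Acta2 (47.6-fold) and Thy1 (11.3-fold), and so were the matrix-remodelling Mmp14 (21.9-fold) and Mmp2 (18.7-fold). Neutrophil genes included S100a8 (234-fold), S100a9 (at least 142-fold), Lcn2 (56.2-fold) and Ltf (at least 36.6-fold) and the attractants Cxcl5 (at least 30.2-fold) and Cxcl2 (at least 2.48-fold), Cxcl2 detected on 1 of the 2 arrays. Macrophage-related genes included Chil3 (at least 123-fold), Gpnmb (at least 52.9-fold) and Lgals3 (37.6-fold), the monocyte chemokine Ccl7 (at least 33.4-fold) and the acute-phase Saa3 (196-fold). Liver genes fell, among them Mup6 (at least 93.8-fold), Mup20 (at least 79.7-fold), Cyp2c50 (at least 73.3-fold), Cyp2c37 (at least 77.3-fold), Gnmt (at least 60.1-fold), Hamp2 (at least 163-fold), Cps1 (at least 33.8-fold), Hpd (at least 23.3-fold) and Cyp2e1 (33.5-fold).

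Calls in the 6-week outer zone numbered 1648, 774 higher and 874 lower (46.97% higher, against 3.55% of 2565 with median scaling), and 72 had no usable fold. Of the stellate-cell and myofibroblast markers 10 of 13 were called higher, and 10 adjusted over the list alone (camera adjusted p = 2.76e-06, and 0.00845 with an estimated correlation). Among the collagens and matrix genes, 16 of 22 were called higher and 0 lower, and 17 and 1 adjusted over the list alone (camera adjusted p = 3.17e-13, and 0.0472 with an estimated correlation). Among the metalloproteinases and inhibitors, 11 of 19 were called higher, and 13 adjusted over the list alone (camera adjusted p = 3.24e-08, and 0.00774 with an estimated correlation). Of the neutrophil markers 16 of 22 were called higher, and 16 adjusted over the list alone (camera adjusted p = 7.17e-12, and 0.0472 with an estimated correlation). Of the TGF-beta and profibrotic signalling genes 7 of 20 were called higher and 1 lower, and 10 and 1 adjusted over the list alone (camera adjusted p = 1.62e-04, and 0.0472 with an estimated correlation). Of the urea cycle and amino acid catabolism genes 19 of 21 were called lower, and 19 adjusted over the list alone (camera adjusted p = 3.28e-15, and 0.0472 with an estimated correlation). The hepatocyte markers had 19 of 25 called lower, and 22 adjusted over the list alone (camera adjusted p = 4.67e-14, and 0.0605 with an estimated correlation). Of 30 lists, 26 passed camera and 12 kept the call with an estimated correlation. The count was 707 without uninfected replicate 1, 856 without uninfected replicate 2 and 827 without 6-week outer-zone replicate 1, and 4.08% of calls in simulated data were unchanged genes.

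The 7-week outer zone, compared with uninfected liver for the same reason, was rich in matrix and stromal transcripts. Timp1 rose at least 345-fold, and matrix genes followed with Col1a2 (224-fold), Col3a1 (131-fold), Col5a1 (118-fold), Fbln2 (at least 108-fold), Col1a1 (at least 80.4-fold) and Lox (at least 47.4-fold). The largest rises also included the calcification inhibitor Mgp (146-fold) and the mucin-type glycoprotein Pdpn (at least 163-fold). Myofibroblast and remodelling genes were Acta2 (64.6-fold), Thy1 (47.4-fold), Mmp14 (47.04-fold) and Mmp2 (42-fold). Chemokines for monocytes and eosinophils rose, with Ccl7 (at least 78.1-fold), Ccl11 (at least 42.05-fold) and Ccl8 (at least 26.1-fold), and so did the macrophage-related Gpnmb (at least 108-fold), Chil3 (at least 78.1-fold) and Lgals3 (54.1-fold). The neutrophil-related S100a8 (87.7-fold), S100a9 (at least 35.8-fold) and Il1b (17.7-fold) were higher than in uninfected liver. Secreted and metabolic liver genes called lower included Cyp2e1 (at least 624-fold), Apoc3 (at least 600-fold), Apoa2 (402-fold), Hamp (at least 302-fold), Mat1a (261-fold), Apoa1 (234-fold), Mup2 (at least 737-fold), Ces1c (at least 350-fold) and Mup6 (at least 332-fold).

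The 7-week outer zone had 1965 called genes, 1070 higher and 895 lower (54.5% higher, against 35.8% of 2167 with median scaling), and all had a usable fold. The collagens and matrix genes had 19 of 22 called higher, and 20 adjusted over the list alone (camera adjusted p = 3.97e-14, and 0.0404 with an estimated correlation). Among the stellate-cell and myofibroblast markers, 10 of 13 were called higher and 1 lower, and 10 and 1 adjusted over the list alone (camera adjusted p = 6.94e-05, and 0.0212 with an estimated correlation). The metalloproteinases and inhibitors had 14 of 19 called higher, and 16 adjusted over the list alone (camera adjusted p = 7.86e-09, and 0.00743 with an estimated correlation). Among the neutrophil markers, 9 of 22 were called higher, and 9 adjusted over the list alone (camera adjusted p = 9.7e-05, and 0.192 with an estimated correlation). For the hepatocyte markers, 24 of 25 were called lower, and 24 adjusted over the list alone (camera adjusted p = 2.35e-26, and 0.0404 with an estimated correlation). Of the fatty acid oxidation genes 10 of 15 were called lower, and 11 adjusted over the list alone (camera adjusted p = 5.69e-09, and 0.0428 with an estimated correlation). Of 30 lists, 21 passed camera and 8 kept the call with an estimated correlation. The number of calls was 1004 without uninfected replicate 1, 1174 without uninfected replicate 2, 1236 without 7-week outer-zone replicate 1 and 1117 without 7-week outer-zone replicate 2.

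For the periphery, the question was whether the rim of the 7-week granuloma is closer to liver or to lesion. It held neutrophil, plasma-cell and matrix transcripts beside liver transcripts. S100a8 was 675-fold and S100a9 at least 491-fold higher, S100a8 with a log2 difference of 9.40 ± 0.72 SE. Genes for neutrophil granule proteins were higher, with Ltf (at least 352-fold) and Camp (at least 120-fold), as were the protease inhibitor Slpi (at least 542-fold) and Mmp9 (at least 38.7-fold), Lcn2 (44.6-fold), Cxcr2 (at least 8.47-fold) and Csf3r (10.9-fold). Plasma-cell and B-cell genes called higher were Mzb1 (at least 283-fold), Pou2af1 (at least 34.3-fold), Jchain (at least 25.2-fold) and Cd79b (at least 13.8-fold). The eosinophil granule gene Prg2 (at least 4.63-fold) was called in this tissue. Collagen and remodelling genes called higher included Col1a2 (56.96-fold), Col3a1 (37.8-fold), Mmp2 (23.7-fold) and Timp1 (at least 4.97-fold), and so were Chil3 (at least 122-fold), Gpnmb (at least 28.9-fold), Lgals3 (22.5-fold) and Lyz2 (17.8-fold). Cxcl2, Il1b (log2 difference 1.74) and Ccl3 (log2 difference 0.72) were not called, and Cxcl2 was detected on 0 arrays of periphery or uninfected liver. Liver genes called lower included the hepcidin gene Hamp2 (162-fold) and the metabolic Cyp2a5 (at least 112-fold), Cyp4a14 (at least 87.4-fold), Acaa1b (75.8-fold), Cyp2b9 (at least 75.03-fold), Cyp2c29 (33.8-fold), Cyp2f2 (33.6-fold) and Abcb11 (25.4-fold), and Cyp2e1 (log2 difference -2.59) was not called.

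In the periphery 808 genes were called, 470 higher and 338 lower (58.2% higher, against 38.3% of 1264 with median scaling and 44.5% of 2654 with the authors' value table). The neutrophil markers had 15 of 22 called higher, and 20 adjusted over the list alone (camera adjusted p = 8.55e-21, and 0.0309 with an estimated correlation). Of the B and plasma cell markers 6 of 11 were called higher, and 9 adjusted over the list alone (camera adjusted p = 1.35e-06, and 0.127 with an estimated correlation). The stellate-cell and myofibroblast markers had 6 of 13 called higher, and 8 adjusted over the list alone (camera adjusted p = 4.08e-04, and 0.0309 with an estimated correlation). The phagocyte oxidase and receptor genes had 8 of 23 called higher, and 10 adjusted over the list alone (camera adjusted p = 2.67e-09, and 0.0175 with an estimated correlation). Among the fatty acid oxidation genes, 5 of 15 were called lower, and 11 adjusted over the list alone (camera adjusted p = 1.87e-09, and 0.0494 with an estimated correlation). Among the cytochrome P450 and xenobiotic genes, 15 of 22 were called lower, and 16 adjusted over the list alone (camera adjusted p = 1.24e-14, and 0.0744 with an estimated correlation). Of the hepatocyte markers 9 of 25 were called lower, and 12 adjusted over the list alone (camera adjusted p = 8.38e-09, and 0.159 with an estimated correlation). Of 30 lists, 22 passed camera and 5 kept the call with an estimated correlation. The periphery count was 200 without uninfected replicate 1, 288 without uninfected replicate 2 and 234 without periphery replicate 2.

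**Figure D3:**
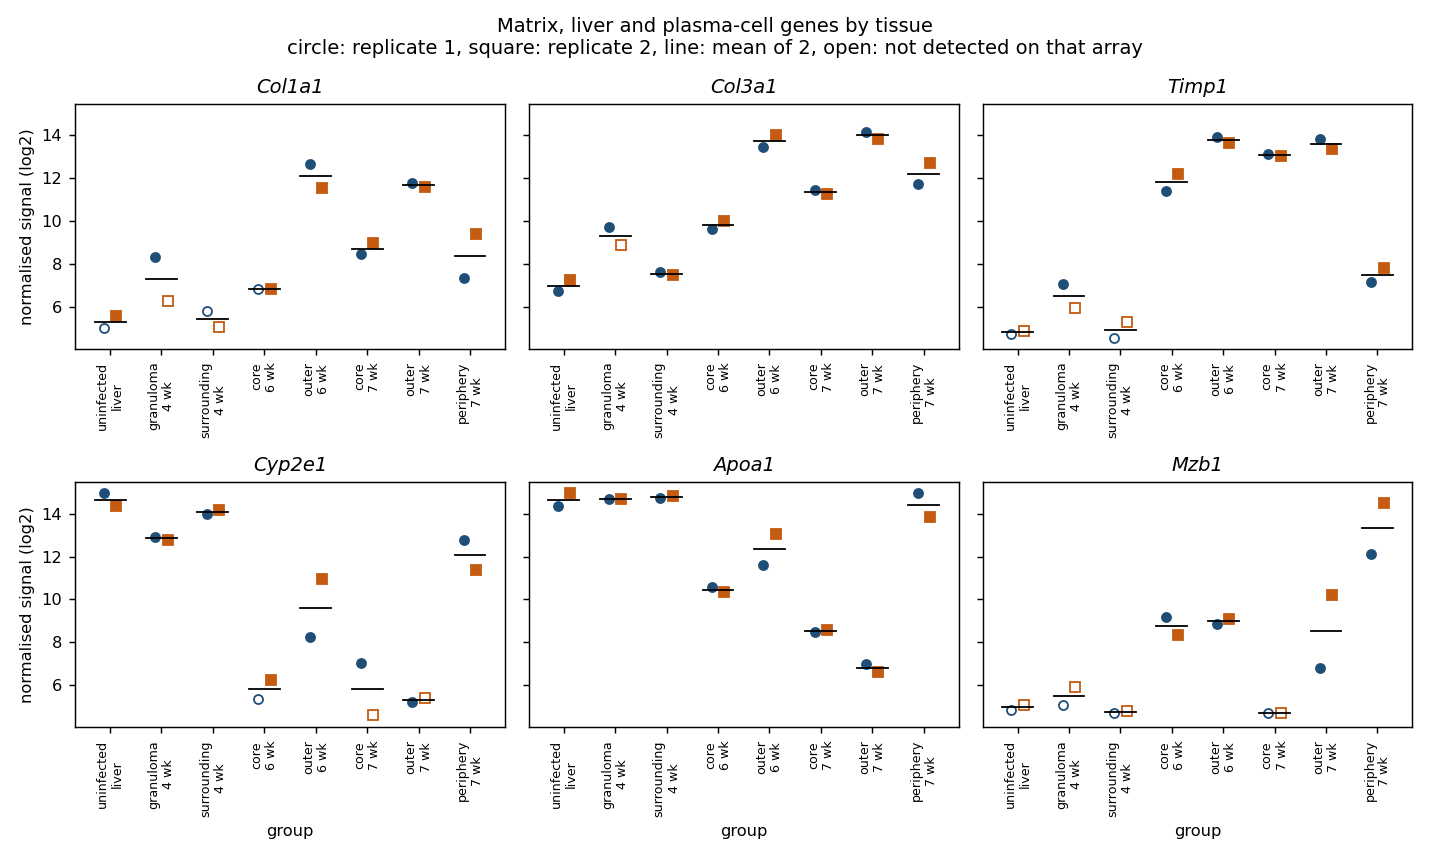
Normalised log2 signal (vertical axis) of Col1a1, Col3a1, Timp1, Cyp2e1, Apoa1 and Mzb1 in the 8 groups, 1 point per array with a line at the group mean and open points where the array did not detect the gene. The collagens and Timp1 were highest in the outer zones, the mean of Apoa1 was 14.40 in the periphery and 14.66 in uninfected liver, and Mzb1 was highest in the periphery.

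The core was then set against the outer zone of the same week to ask how the granuloma is layered. At 6 weeks the core held more inflammatory transcripts and the outer zone more matrix, endothelial and acute-phase ones. Cxcl2 was at least 80.1-fold higher in the core, with a log2 difference of 7.03 ± 0.42 SE, followed by Ccl3 (at least 59.6-fold), Ccrl2 (at least 18.2-fold), Cstdc4 (at least 21.03-fold), Ccl4 (40.5-fold) and Hcar2 (at least 39.7-fold). The core also had more of the neutrophil genes Clec4d (at least 26.9-fold), Hdc (20.2-fold), Csf3r (10.2-fold) and S100a9 (4.86-fold), the inflammatory Tnf (at least 6.92-fold), Il1b (10.6-fold) and Nos2 (at least 7.18-fold), the stress regulator Atf3 (at least 6.73-fold) and the metalloproteinases Adam8 (at least 8.02-fold) and Mmp13 (11.6-fold). S100a8 (log2 difference 1.35) was not called, and Il1b was not called with a replicate block (adjusted p = 0.0632). In the outer zone the collagens and their processing enzymes were higher, as Col5a1 (at least 22.2-fold), Col1a1 (at least 22.6-fold), Col6a1 (at least 17.1-fold), Col3a1 (15.3-fold), Loxl1 (at least 10.8-fold) and Lox (at least 5.64-fold) were lower in the core. Spon2 (at least 12.7-fold), Olfml3 (at least 11.7-fold) and Fstl1 (at least 7.78-fold) and the mesenchymal Acta2 (10.2-fold), Cygb (at least 8.88-fold) and Pdgfra (at least 6.45-fold) were also lower in the core, with the stromal chemokine Cxcl12 (at least 10.3-fold) and the attractant Cxcl5 (at least 7.32-fold). So were the endothelial Esam (at least 9.74-fold) and Egfl7 (at least 8.10-fold), the acute-phase Hamp (at least 7.72-fold) and Serpina3n (6.91-fold) and the hepatocyte genes Trf (5.92-fold) and Fga (5.12-fold).

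Between the 6-week zones 473 genes were called, 195 higher in the core and 278 lower (41.2% higher, against 100% of 1 with median scaling). For the collagens and matrix genes, 16 of 22 were called lower, and 17 adjusted over the list alone (camera adjusted p = 2.28e-19, and 0.0199 with an estimated correlation). For the stellate-cell and myofibroblast markers, 5 of 13 were called lower, and 8 adjusted over the list alone (camera adjusted p = 2.76e-05, and 0.0150 with an estimated correlation). Among the classically activated macrophage genes, 3 of 11 were called higher, and 5 adjusted over the list alone (camera adjusted p = 4.69e-08, and 0.0150 with an estimated correlation), and of the phagocyte oxidase and receptor genes 7 of 23 were, and 12 over the list alone (1.79e-11, and 0.00735). For the neutrophil markers, 9 of 22 were called higher and 1 lower, and 11 and 1 adjusted over the list alone (camera adjusted p = 2.63e-11, and 0.0760 with an estimated correlation). Called lower were 8 of 18 acute phase genes (camera adjusted p = 6.28e-07, and 0.281 with an estimated correlation), 5 of 19 endothelial markers (0.00230, and 0.313) and 5 of 25 hepatocyte markers (0.0531, and 0.647). Of 30 lists, 14 passed camera and 4 kept the call with an estimated correlation. The count was 280 without 6-week core replicate 1, 1111 without 6-week core replicate 2 and 307 without 6-week outer-zone replicate 1. It fell to 1 with median scaling and 0 when only these zones' 4 arrays were fitted, and 49.2% of calls in simulated data were unchanged genes.

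At 7 weeks the core was again the inflammatory zone and the outer zone the matrix-rich one. Cxcl2 was 170-fold higher in the core, with a log2 difference of 7.41 ± 0.42 SE, and the butyrate receptor gene Hcar2 was at least 68.1-fold higher. Neutrophil genes higher in the core were Lcn2 (49.5-fold), Hdc (47.05-fold), Stfa2 (at least 31.04-fold), Retnlg (39.6-fold), S100a9 (20.8-fold), Cxcr2 (at least 11.8-fold) and Csf3r (6.89-fold) and the receptor Mrgpra2b (49.6-fold). Inflammatory genes included Ccl3 (48.3-fold), Ptgs2 (at least 18.7-fold), Tnf (19.2-fold), Il1b (16.9-fold) and Chil1 (49.98-fold) and the cytokines Il10 (at least 15.4-fold) and Il23a (at least 7.94-fold). Low-oxygen and glycolysis genes called higher included Egln3 (27.5-fold), Slc2a1 (14.2-fold) and Aldoa (5.24-fold), as were the early-response Dusp1 (10.97-fold) and Atf3 (10.2-fold). The stromal and lymphoid chemokines Cxcl12 (at least 26.3-fold), Ccl21a (at least 11.1-fold) and Ccl11 (at least 12.8-fold) were lower in the core. Matrix and stellate-cell genes lower in the core were Loxl1 (20.8-fold), Col6a1 (14.8-fold), Col1a2 (9.22-fold), Col3a1 (6.26-fold), Mmp2 (at least 19.2-fold), Thy1 (at least 14.5-fold), Cygb (at least 13.8-fold) and Pdgfra (at least 7.18-fold), together with Olfml3 (at least 10.7-fold), Dkk3 (at least 14.4-fold) and Mxra8 (at least 8.62-fold). Endothelial Egfl7 (at least 12.3-fold) and Plvap (at least 6.42-fold), the complement gene C1qc (at least 8.36-fold) and the cell-cycle gene Ccnd1 (at least 6.85-fold) were lower in the core as well.

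Core and outer zone at 7 weeks differed in 600 genes, 212 higher in the core and 388 lower (35.3% higher, against 1.78% of 1743 with median scaling). Of the neutrophil markers 16 of 22 were called higher, and 18 adjusted over the list alone (camera adjusted p = 5.92e-24, and 0.0194 with an estimated correlation). Among the neutrophil chemoattractants, 4 of 8 were called higher and 1 lower, and 7 and 1 adjusted over the list alone (camera adjusted p = 1.94e-08, and 0.0194 with an estimated correlation). Among the hypoxia and glycolysis genes, 4 of 16 were called higher, and 9 adjusted over the list alone (camera adjusted p = 4.11e-10, and 0.0202 with an estimated correlation). Of the immediate early and heat shock genes 5 of 14 were called higher, and 7 adjusted over the list alone (camera adjusted p = 4.94e-07, and 0.0260 with an estimated correlation). Of the collagens and matrix genes 13 of 22 were called lower, and 21 adjusted over the list alone (camera adjusted p = 5.25e-14, and 0.0260 with an estimated correlation). Of the cell cycle genes 3 of 18 were called lower, and 8 adjusted over the list alone (camera adjusted p = 2.34e-04, and 0.0300 with an estimated correlation). Of 30 lists, 14 passed camera and 9 kept the call with an estimated correlation. With 1 array fewer the count was 201 without 7-week core replicate 1, 154 without 7-week core replicate 2, 214 without 7-week outer-zone replicate 1 and 162 without 7-week outer-zone replicate 2.

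The outer zone against the periphery at 7 weeks asks where lesion gives way to liver. The outer zone had more Timp1 (69.4-fold, log2 difference 6.12 ± 0.49 SE) and more of the matrix genes Col15a1 (at least 41.9-fold), Fbln2 (25.6-fold), Col5a1 (16.8-fold) and Col1a1 (9.95-fold), the contractile Actg2 (at least 35.5-fold) and Acta2 (9.72-fold), the chemokines Ccl7 (41.99-fold) and Ccl11 (29.3-fold) and Saa3 (28.4-fold). With a replicate block Col5a1 was not called (adjusted p = 0.0525). It had less of the liver's secreted proteins, with Apoa1 (196-fold), Azgp1 (at least 136-fold), Mug1 (at least 122-fold), Fga (160-fold) and Serpina1e (150-fold) lower, and of the metabolic Mat1a (120-fold) and Cyp2e1 (at least 104-fold) and acute-phase Orm2 (143-fold) and Hpx (129-fold). Neutrophil granule genes were lower in the outer zone too: Camp (at least 71.3-fold), Ltf (58.4-fold), Mpo (at least 55.2-fold) and Ngp (at least 34.95-fold), with S100a9 (13.7-fold) and S100a8 (7.69-fold). The plasma-cell genes Mzb1 (28.2-fold), Pou2af1 (at least 21.1-fold) and Jchain (16.9-fold), the liver macrophage gene Vsig4 (at least 9.40-fold) and the red-cell Hba-a1 (8.24-fold) were lower.

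Over the whole comparison 328 genes were called, 86 higher in the outer zone and 242 lower (26.2% higher, against 13.2% of 326 with median scaling). The share was 50.9% of 668 with the authors' value table, 44.7% of 1006 with array weights, 44.1% of 465 without background correction and 38.4% of 417 with normexp at offset 50. Among the hepatocyte markers, 20 of 25 were called lower, and 21 adjusted over the list alone (camera adjusted p = 1.2e-40, and 0.0309 with an estimated correlation). Among the neutrophil markers, 0 of 22 were called higher and 10 lower, and 1 and 12 adjusted over the list alone (camera adjusted p = 5.18e-16, and 0.0430 with an estimated correlation). Among the B and plasma cell markers, 5 of 11 were called lower, and 7 adjusted over the list alone (camera adjusted p = 1.97e-08, and 0.0681 with an estimated correlation). Among the collagens and matrix genes, 6 of 22 were called higher, and 13 adjusted over the list alone (camera adjusted p = 5.57e-14, and 0.0430 with an estimated correlation). Of the acute phase genes 1 of 18 were called higher and 12 lower, and 1 and 14 adjusted over the list alone (camera adjusted p = 4.42e-20, and 0.0430 with an estimated correlation). Of 30 lists, 21 passed camera and 9 kept the call with an estimated correlation. The count was 132 without 7-week outer-zone replicate 1, 143 without 7-week outer-zone replicate 2 and 134 without periphery replicate 1.

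The core against the periphery at 7 weeks asks whether neutrophil transcripts differ between the centre and the rim. They did, and in both directions. Cxcl2, not detected in the periphery, was at least 336-fold higher in the core. Next came the inflammatory Ccl3 (213-fold), Ccl4 (211-fold), Il1b (89.9-fold), Tnf (at least 28.4-fold) and Ptgs2 (at least 22.5-fold) and Il10 (at least 17.7-fold). The neutrophil genes Clec4d (35.01-fold), Hdc (22.2-fold) and Csf3r (4.13-fold) and the protease inhibitor Csta2 (at least 85.3-fold) were higher in the core, and the granule genes Camp (at least 33.9-fold) and Mpo (at least 18.97-fold) lower. Higher in the core were Mmp12 (101-fold), Mmp13 (47.8-fold), Cd14 (46-fold), Timp1 (47.8-fold), Saa3 (62.3-fold) and the low-oxygen Slc2a1 (35.2-fold) and Egln3 (33.7-fold). Macrophage markers had 2 of 19 called higher, 4 lower. The core had less of the plasma-cell Mzb1 (at least 85.9-fold) and Jchain (at least 7.67-fold), the class II Cd74 (11.6-fold) and H2-Aa (10.5-fold), the stromal Cxcl12 (at least 23.9-fold), the red-cell Hba-a1 (16.2-fold) and the liver genes Mug1 (at least 65.8-fold), Fgg (at least 54.6-fold), Cyp2e1 (at least 32.6-fold) and Apoh (at least 32.2-fold).

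This last pair of zones differed in 929 genes, 328 higher in the core and 601 lower (35.3% higher, against 1.51% of 3172 with median scaling), with 114 lacking a usable fold. The neutrophil markers had 8 of 22 called higher and 4 lower, and 9 and 5 adjusted over the list alone (camera adjusted p = 0.00569, and 0.425 with an estimated correlation). The neutrophil chemoattractants had 5 of 8 called higher, and 5 adjusted over the list alone (camera adjusted p = 1.71e-08, and 0.0163 with an estimated correlation). The hypoxia and glycolysis genes had 8 of 16 called higher, and 10 adjusted over the list alone (camera adjusted p = 6.48e-11, and 0.0163 with an estimated correlation). Among the immediate early and heat shock genes, 7 of 14 were called higher, and 7 adjusted over the list alone (camera adjusted p = 1.6e-08, and 0.0163 with an estimated correlation). The B and plasma cell markers had 7 of 11 called lower, and 8 adjusted over the list alone (camera adjusted p = 7.03e-06, and 0.185 with an estimated correlation). Of 30 lists, 18 passed camera and 6 kept the call with an estimated correlation. Fewer arrays gave 434 without 7-week core replicate 1, 448 without 7-week core replicate 2, 524 without periphery replicate 1 and 556 without periphery replicate 2, and 1.08% of calls in simulated data were unchanged genes.

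**Figure D4:**
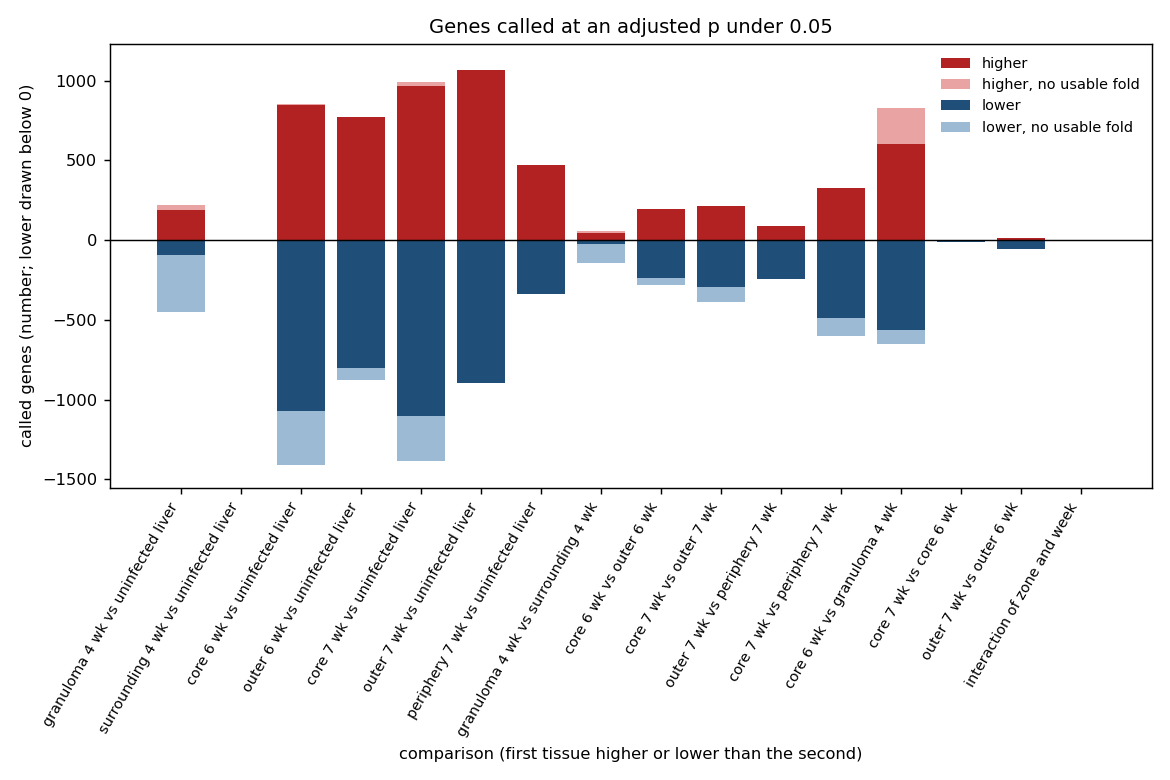
Number of genes called higher (bars above 0) and lower (bars below 0) in each of the 16 comparisons at an adjusted p under 0.05, the part without a usable fold in a paler shade. The tissue around the 4-week granuloma and the interaction had 0 calls and the 7-week core against uninfected liver had the most, 2377.

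The 6-week core was set against the 4-week granuloma, which was not zoned, so week and region cannot be separated. Neutrophil and inflammatory genes called higher included S100a8 (at least 103-fold), S100a9 (at least 90.2-fold), Hdc (at least 34.1-fold), Retnlg (at least 26.02-fold) and Fpr2 (at least 46.5-fold), with Cxcl2 (at least 40.7-fold), Il1b (at least 32.5-fold), Ccl3 (at least 29.3-fold) and Ccl4 (at least 75.7-fold). No granuloma array detected S100a9. Tissue-repair and macrophage genes included Tgfbi (at least 29.4-fold), Saa3 (at least 48.01-fold), Timp1 (at least 12.4-fold), Chil3 (at least 36.5-fold), Mmp12 (at least 8.20-fold) and Tlr2 (at least 5.52-fold), and glucose-use genes Pkm (at least 17.4-fold) and Slc2a1 (at least 11.03-fold). Liver genes called lower included Mup2 (at least 176-fold), Mat1a (at least 65.2-fold), Cyp2f2 (at least 57.9-fold), Cyp2e1 (at least 46.9-fold), Mup6 (at least 83.9-fold), Acaa1b (at least 35.4-fold) and Hpd (at least 20.3-fold), and so did Cxcl9 (at least 5.65-fold) and Col18a1 (at least 15.01-fold).

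In this comparison 1478 genes were called, 827 higher at 6 weeks and 651 lower (55.95% higher, against 76.2% of 21 with median scaling), and 312 had no usable fold. For the neutrophil markers, 16 of 22 were called higher, and 18 adjusted over the list alone (camera adjusted p = 7.63e-16, and 0.0511 with an estimated correlation), and of the neutrophil chemoattractants 6 of 8 were, and 6 over the list alone (1.74e-06, and 0.0446). For the phagocyte oxidase and receptor genes, 19 of 23 were called higher, and 20 adjusted over the list alone (camera adjusted p = 9.38e-13, and 0.00567 with an estimated correlation). The hepatocyte markers had 0 of 25 called higher and 22 lower, and 1 and 22 adjusted over the list alone (camera adjusted p = 5.82e-19, and 0.0573 with an estimated correlation). Each group has a dim array, and with 200 genes changed 78.04% of calls in simulated data were unchanged genes. The count was 21 with median scaling, 2 with the authors' value table and 0 when only these 4 arrays were fitted.

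Comparing weeks within a zone asks whether the granuloma was still changing. In the core 10 genes were called between 6 and 7 weeks, 1 higher and 9 lower at 7 weeks (10% higher, against 50% of 30 without background correction, 40.9% of 22 with normexp at offset 50 and 33.3% of 3 with array weights). Called lower were the class II gene H2-Aa (11.3-fold), the interferon-related Gbp2 (10.4-fold), Irf1 (6.54-fold), Ifi47 (at least 8.05-fold) and Isg15 (at least 3.17-fold), Isg15 detected on 1 of the 2 arrays at 6 weeks, and the T-cell chemokine Ccl5 (at least 7.40-fold). Of the interferon response genes 3 of 21 were called lower, and 8 adjusted over the list alone (camera adjusted p = 2.69e-15, and 0.166 with an estimated correlation), and of the class II antigen-presentation genes 1 of 10 were, and 6 over the list alone (2.84e-09, and 0.170). Markers of other cells fell too. Adjusted over the list alone, 10 of 25 hepatocyte markers (camera adjusted p = 1.38e-10, and 0.257 with an estimated correlation) and 1 of 7 erythroid and platelet markers (0.0222, and 0.170) were called lower, and the latter list did not pass with median scaling. The acute-phase genes Orm2 (at least 9.17-fold) and Hpx (10.04-fold) were lower and the smooth-muscle actin Actg2 (at least 5.42-fold) was higher. The collagens and matrix genes had 0 of 22 called higher, and 8 adjusted over the list alone (camera adjusted p = 5.59e-09, and 0.170 with an estimated correlation). The count was 19 without 6-week core replicate 1, 847 without 6-week core replicate 2, 2 without 7-week core replicate 1 and 1 without 7-week core replicate 2, 0 with median scaling and 0 when only these 4 arrays were fitted, and 28.1% of calls in simulated data were unchanged genes.

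In the outer zone 65 genes were called between the weeks, 11 higher and 54 lower at 7 weeks (16.9% higher, against 100% of 6 with median scaling). All 18 calls with the authors' value table were higher too. Every gene named here kept its direction on both of these scales, and none of those called lower was called there. Called lower were the acute-phase and secreted-protein genes Hamp (at least 94.8-fold), Orm2 (101-fold), Hpx (100-fold), Orm1 (94.8-fold), Fga (91.3-fold), Trf (48.9-fold) and Apoa1 (46.8-fold). The neutrophil genes Lcn2 (35.97-fold) and Mpo (at least 9.04-fold), the liver macrophage gene Vsig4 (at least 14.6-fold), the class II gene H2-Aa (4.95-fold) and the red-cell Hba-a1 (9.77-fold) were also lower. The matrix regulators Mgp (32.2-fold), Thbs2 (at least 7.44-fold), Grem1 (at least 4.77-fold) and Ccn5 (at least 2.47-fold) were higher, as were Fcrls (at least 6.30-fold) and the chemokine Ccl12 (at least 4.22-fold). With a replicate block Mgp, Thbs2 and Ccl12 were not called (adjusted p = 0.0569, 0.0699 and 0.0524). Among the acute phase genes, 9 of 18 were called lower, and 12 adjusted over the list alone (camera adjusted p = 1.76e-30, and 0.0524 with an estimated correlation), and of the hepatocyte markers 11 of 25 were, and 12 over the list alone (9.86e-30, and 0.0524). Of the erythroid and platelet markers 1 of 7 were called lower, and 1 adjusted over the list alone (camera adjusted p = 1.85e-05, and 0.0442 with an estimated correlation). The count was 6 with median scaling and 0 when only these 4 arrays were fitted, and 7.87% of calls in simulated data were unchanged genes.

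The interaction of zone and week asked if the layering changed, with the same limit on zones. No gene was called by limma (464 had an unadjusted p under 0.05), while other choices of model, filter or scaling called from 0 to 20: 15 among genes detected on all 16 arrays, 11 with a trended robust fit and 20 with the 3 dimmest arrays left out. Of 30 lists, 12 passed camera and 0 kept the call with an estimated correlation. Leaving out 1 array called 5 without 6-week core replicate 1, 114 without 6-week core replicate 2 and 1 without 6-week outer-zone replicate 1.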

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

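The list differences below come from tests planned before the data were seen, and the count of unnamed probes was chosen after them. The contrast between core and outer zone differed between 6 and 7 weeks for 12 lists by camera with a preset correlation. The difference between core and outer zone shifted toward the core at 7 weeks, with adjusted camera p-values of 1.66e-15 for acute phase genes, 2.04e-08 for hepatocyte markers, 2.29e-07 for neutrophil markers, 0.000433 for complement and coagulation genes, 0.00171 for cytochrome P450 and xenobiotic genes, 0.00462 for collagens and matrix genes, 0.0147 for hypoxia and glycolysis genes and 0.0384 for fatty acid oxidation genes. It shifted toward the outer zone for interferon response genes (2.12e-09), other chemokines (0.00171), cell cycle genes (0.0147) and B and plasma cell markers (0.0278). A shift toward the core was not always a rise there: from 6 to 7 weeks the median of acute phase genes was -0.82 in the core and -4.11 in the outer zone, that of hepatocyte markers -1.15 and -1.87, and that of neutrophil markers -0.05 and -1.28, while that of collagens and matrix genes was 1.55 and 0.75. None of the 12 held with an estimated correlation, where the smallest adjusted p was 0.299, or with fry, where it was 0.155. No gene passed limma for this difference, with 464 at an unadjusted p under 0.05, so the change stays unsettled.

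Probes without a gene symbol, which no comparison used, were called as well. Of 698 such probes past the detection filter, 149 were called higher than in uninfected liver in at least 1 tissue, 97 of them in the 7-week core and 0 in the surrounding tissue at 4 weeks. The 97 are 13.9% of these probes, against 11.1% of probes with a symbol in the same fit, so the count shows nothing particular to them. No explanation of the list differences was tested.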

How the results depend on the processing

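The fit without the 3 dimmest arrays and the count of only genes with a usable fold were chosen after the data had been seen, and all other alternatives were planned. Camera sets a list against other genes, so a scaling that moves all genes of an array alike tests it little: of 80 list results 78 kept direction and call with median scaling, 80 with a replicate block and 70 with the authors' value table. With an estimated correlation only 69 of 263 list calls held, and 0 in 5 of the comparisons with calls. Of 414 named gene results, 409 kept theirs with normexp at offset 50, 403 without background correction, 406 with a replicate block, 390 without a detection filter, 336 with array weights, 284 with median scaling, 282 with the authors' value table and 274 when only the groups compared were fitted. Counts of called genes depended on processing, and where no cause is given below the cause was not tested. A tissue named alone was compared with uninfected liver.

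With median scaling the calls numbered 5621 in the 4-week granuloma, 9 in the surrounding tissue, 4416 in the 6-week core, 2565 in the 6-week outer zone, 4125 in the 7-week core, 1264 in the periphery, 319 in granuloma against surroundings, 1 in core against outer zone at 6 weeks, 1743 in core against outer zone at 7 weeks, 3172 in core against periphery, 21 in 6-week core against 4-week granuloma, 0 in core between weeks and 6 in outer zone between weeks. Their shares of higher calls stand with each comparison. Between tissues of infected liver the median gene moved from -0.36 to -1.02 in granuloma against surroundings, from -0.20 to -0.46 in core against outer zone at 6 weeks and from -0.23 to -1.35 at 7 weeks, from 0.06 to -0.11 in outer zone against periphery, from -0.25 to -1.51 in core against periphery, from 0.13 to 0.24 in 6-week core against 4-week granuloma, from 0.19 to 1.05 in outer zone between weeks and from -0.05 to -0.87 in the interaction. Direction reversed in the 4-week granuloma, with log2 differences of -1.54 for Lcn2, -0.12 for Ccl5, -0.81 for Lgals3, -1.53 for Ctss, -0.008 for Clec7a, -0.52 for Prf1, -0.31 for H2-Eb1, -0.29 for H2-Aa, -0.99 for Acta2, -0.56 for Vim, -1.25 for Col3a1, -0.86 for Oasl2, -0.99 for Gbp2. With the authors' value table the calls numbered 4844 in the 4-week granuloma, 631 in the surrounding tissue, 4488 in the 6-week core, 3636 in the 6-week outer zone, 4459 in the 7-week core, 3574 in the 7-week outer zone, 2654 in the periphery, 523 in granuloma against surroundings, 0 in core against outer zone at 6 weeks, 1074 in core against outer zone at 7 weeks, 668 in outer zone against periphery, 2540 in core against periphery, 2 in 6-week core against 4-week granuloma, 0 in core between weeks and 18 in outer zone between weeks. Where not given with the comparison, the share of higher calls was then 0% in granuloma against surroundings and 12.4% in core against outer zone at 7 weeks. Direction reversed in the 4-week granuloma, with log2 differences of -0.55 for Lcn2, -0.13 for Lgals3, -0.49 for Ctss, -0.36 for Prf1, -0.28 for H2-Aa, -0.092 for Acta2, -0.58 for macrophage markers.

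Testing only genes detected on all 16 arrays, which leaves 509 genes and drops those lost from a tissue, so that its shares of higher calls are not compared, gave 140 in the 4-week granuloma, 2 in the surrounding tissue, 307 in the 6-week core, 293 in the 6-week outer zone, 311 in the 7-week core, 317 in the 7-week outer zone, 236 in the periphery, 48 in granuloma against surroundings, 122 in core against outer zone at 6 weeks, 144 in core against outer zone at 7 weeks, 102 in outer zone against periphery, 155 in core against periphery, 179 in 6-week core against 4-week granuloma, 25 in core between weeks, 30 in outer zone between weeks and 15 in the interaction. No detection filter gave 2 in the surrounding tissue and 371 in granuloma against surroundings. Testing every probe gave 1039 in the 4-week granuloma and 327 in granuloma against surroundings. A replicate block within week gave 910 in granuloma against surroundings, 1037 in core against outer zone at 7 weeks, 1504 in core against periphery and 2 in the interaction. Fitting only the groups compared, which leaves fewer arrays for the spread, gave 0 in the 4-week granuloma, 2 in the surrounding tissue, 4125 in the 7-week core, 4462 in the 7-week outer zone, 2504 in the periphery, 0 in granuloma against surroundings, 0 in core against outer zone at 6 weeks, 1377 in core against outer zone at 7 weeks, 640 in outer zone against periphery, 1532 in core against periphery, 0 in 6-week core against 4-week granuloma, 0 in core between weeks and 0 in outer zone between weeks. Trended robust eBayes gave 7 in the surrounding tissue, 30 in core between weeks, 105 in outer zone between weeks and 11 in the interaction, and array weights gave 0 in the 4-week granuloma, 230 in the surrounding tissue, 4341 in the 7-week core, 4481 in the 7-week outer zone, 2946 in the periphery, 0 in granuloma against surroundings, 67 in core against outer zone at 6 weeks, 1911 in core against outer zone at 7 weeks, 1006 in outer zone against periphery, 2071 in core against periphery, 332 in 6-week core against 4-week granuloma and 3 in core between weeks. Normexp at offset 50 gave 22 in core between weeks and 1 in the interaction, and no background correction gave 30 in core between weeks and 5 in the interaction. An adjusted p under 0.01, which is stricter by construction, gave 99 in the 4-week granuloma, 1358 in the 6-week core, 871 in the 6-week outer zone, 1471 in the 7-week core, 1171 in the 7-week outer zone, 321 in the periphery, 10 in granuloma against surroundings, 171 in core against outer zone at 6 weeks, 214 in core against outer zone at 7 weeks, 179 in outer zone against periphery, 469 in core against periphery, 848 in 6-week core against 4-week granuloma, 3 in core between weeks and 30 in outer zone between weeks.

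Without the 3 dimmest arrays the calls numbered 1502 in the 4-week granuloma, 778 in granuloma against surroundings, 751 in core against outer zone at 6 weeks, 2480 in 6-week core against 4-week granuloma, 338 in core between weeks, 165 in outer zone between weeks and 20 in the interaction. Counting only genes with a usable fold gave 282 in the 4-week granuloma and 72 in granuloma against surroundings. Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 10 to 2827 in the 4-week granuloma, 1242 to 3036 in the 6-week core, 707 to 1780 in the 6-week outer zone, 1348 to 1616 in the 7-week core, 1004 to 1236 in the 7-week outer zone, 200 to 624 in the periphery, 0 to 2493 in granuloma against surroundings, 280 to 1111 in core against outer zone at 6 weeks, 154 to 214 in core against outer zone at 7 weeks, 132 to 321 in outer zone against periphery, 434 to 556 in core against periphery, 1362 to 2369 in 6-week core against 4-week granuloma, 1 to 847 in core between weeks, 21 to 122 in outer zone between weeks and 0 to 114 in the interaction. Without replicate 1 of the 4-week granuloma, Il1b was called lower than in the surroundings, at a log2 difference of -1.77, while without replicate 2 it lay at 1.91 and was not called. Signal over background limits the rest: a gene undetected on a dim array may have a bounded fold or none. No fold was usable for 389 of 671 calls in the 4-week granuloma and 0 of 1965 in the 7-week outer zone.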

Other observations

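All tests below were chosen after the values had been seen, so what they leave open are hypotheses. Across zones the data show a core with Cxcl2 and Il1b, a collagen-rich outer zone, S100a8 in every late zone, and a periphery that combines neutrophil granule and plasma-cell transcripts with liver expression. The 4-week granuloma had no called S100a8 or Cxcl2, unlike the later cores, but 1 of its 2 arrays was the dimmest of all.

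Neutrophil granule genes were higher in the periphery than in the outer zone at 7 weeks, as Ltf, Camp, Ngp, Mpo and Elane were. More blood, of the composition found in uninfected liver, stays open, because these 5 genes were picked after their values were known. Against uninfected liver Hba-a1, a globin gene, differed by 1.87 ± 0.67 SE (adjusted p = 0.103). The median of the 5, at lower bounds, exceeded this by 4.10 log2 units. In the outer zone against the periphery the 5 differed by -6.39 to -4.45 and Hba-a1 by -3.04 (adjusted p = 0.0235). Whether neutrophil precursors lie at the rim stays open: of 4 genes of early granulocytes, Prtn3, Ctsg, Ms4a3 and Fcnb, 3 were called higher there than both in uninfected liver and in the outer zone, but these genes were picked after their values were known, so this count decides nothing. Blood whose cells changed during infection was not tested either.

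Liver genes did not fall together in the periphery. The median of 22 cytochrome P450 and xenobiotic genes was -3.28 log2 units against uninfected liver and that of 24 complement and coagulation genes was -1.38, a difference of -1.90, with -2.54 on 1 slide and -1.75 on the other, and of -1.94 with median scaling. Fewer hepatocytes in the dissected tissue as the whole cause are argued against, since that would lower both lists alike. Compression of bright probes is argued against too, because 145 pairs of genes within 1 log2 unit of each other in uninfected liver differed by a median of -1.82. Lower expression of drug-metabolising genes within hepatocytes was not tested, and neither was complement made by other cells.

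More genes were called lower than higher in the 4-week granuloma, but without a detection filter 50.4% of calls were higher. A detection limit is a possible explanation, as 79.5% of the genes called lower had no usable fold on these dim arrays. Loss of hepatocytes stays open. The 25 hepatocyte markers had a median log2 difference of 0.0171 (SD 1.11) against -2.38 for the genes called lower, yet with median scaling these were -3.71 and -3.27.

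The eosinophil gene Prg2 was called only in the periphery against uninfected liver, at least 4.63-fold higher with an adjusted p of 0.0164, and Retnla was called in no comparison.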
